A study of Mus musculus with 30 samples.

How the data were processed

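Gene expression was measured in 30 samples of total RNA, a spleen and a brain sample from each of 15 mice, on 1-colour Illumina WG-6 v2 BeadChips, which read 45281 probes per sample. Per the labels, the samples were hybridised in random order to 5 BeadChips of 6 arrays each, without technical replicates, so each array is 1 mouse. The labels give 3 groups of mice, each in 2 tissues: 3 uninfected untreated mice, 3 infected mice given saline and 9 infected mice given IDR-1018. They also give the mouse number, the BeadChip of each array and, for brain, whether the front or the back of the brain was sampled. The groups held the brain parts unequally: front samples came from 2 of the 3 uninfected, 1 of the 3 saline-treated and 5 of the 9 IDR-1018-treated mice.

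The deposited signals are intensity values on a linear scale, 1 per probe and array, and the values show no background subtraction and no normalisation between arrays. The authors deposited a detection p-value with each signal, per the file headers. Another deposited set of values holds the authors' processed log2 values of the same arrays. BeadStudio and limma are named per the submitters' processing notes, and their versions and settings are not given in the sources used here. In that set the arrays of a tissue share nearly the same quantiles, with medians of 6.07 to 6.12, and the ranks of the probes matched those of the signals on each array (rank correlation 1 after rounding). It was used as an alternative. No column of another sample was present.

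Everything below was computed from the deposited signals in R 4.3.3 with limma 3.58.1, and the R packages jsonlite 2.0.0 and data.table (version 1.17.8) read the files. Signals of 1 tissue at a time were background-corrected, quantile normalised and put on the log2 scale with neqc, using the detection p-values and an offset of 16. A probe was kept where its detection p was under 0.05 in at least 3 arrays of the tissue. For genes with several probes, the probe with the highest mean was kept. This left 14683 probes tested in spleen and 15529 in brain. The tissue differences used all 30 arrays normalised together and 17403 probes. The words gene and genes below stand for these probes, including probes with no symbol here.

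Probes were named through the platform annotation, which gave 1 gene symbol for 34885 probes, several for 18 and none for 10378. Symbols were checked through the Entrez gene identifier, which changed 0 of them, and 34807 probes had an identifier in the gene table of the mouse assembly GRCm38.p6, which was used for names alone. No name was drawn from a probe with several symbols. Because the build behind the probe design is not given in the sources used here, no coordinates are printed.

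Each tissue was fitted with lmFit and eBayes on its 15 arrays, so that all 3 groups shared 1 estimate of the spread. The brain fit had the part of the brain as a covariate. The comparisons were saline-treated infected minus uninfected (infection), IDR-1018-treated minus saline-treated infected (IDR-1018), and IDR-1018-treated infected minus uninfected. Differences between the tissues were tested as interaction terms on all 30 arrays. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Errors written with ± are standard errors of the fit unless marked SD, and a log2 change of infection rests on 3 mice against 3, of IDR-1018 on 9 against 3. Brain levels per mouse are given after the fitted difference between front and back was taken off. Where no array of a group detected a probe, the change is a lower bound, set against the lowest detected signal of each array and written as at least a given fold.

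There were 38 gene lists of responses, pathways and cell types, holding 842 gene entries, of which 764 matched a symbol on the array. Lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, fry, and an exact two-sided permutation test of the list medians per array. The smallest p that test can give is 0.1 for 3 mice against 3 and 0.00909 for 9 against 3. Camera at the preset correlation also called lists when the arrays were split in other ways. The median was 9 lists for infection and 6 for IDR-1018 in spleen, and 5 and 3 in brain. A call at that setting alone therefore does not exclude chance. Members were also counted with p-values adjusted over the list alone. The list value of an array is the median over members of the log2 level relative to the mean of the uninfected mice.

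The groups, main fits, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. Under that rule, the text may name, for infection and IDR-1018 in each tissue, the 8 largest rises and falls among genes past the threshold or, where none passed, the 5 genes with the smallest p in each direction. It may also name up to 4 members with the smallest p of each list that was called or held a called gene, and the 5 largest changes in each direction of the other comparisons. For front against back, it may name members of the forebrain and of the cerebellum and brainstem lists among those 5. Genes named outside the rule are said to be chosen after their values were seen.

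The alternatives were the deposited log2 values, no background correction, median scaling, 2 other filters, all probes, BeadChip as a fixed or random block, array weights, another variance model, fits of 2 groups alone, both tissues normalised together, no brain covariate, front or back samples alone, the mouse as a block across tissues, and each array left out in turn. Added after seeing the data were the permutation test of list medians, the brain lists in front or back samples alone, the spleen without the 3 arrays of BeadChip 5, and the median of the exocrine pancreas list as a covariate in spleen. The mouse number pairs the tissues, because the labels give a spleen and a brain sample of the same animal. The 2 tissues of a mouse did not deviate together: over 12243 genes, the median correlation of their deviations from the group means was -0.0257, against 8.96e-04 between different mice, and 3 of the 15 mice were over 0.1.

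The scripts were tested on simulated arrays with known changes. For infection in spleen, 47 of 50 genes lowered and 49 of 50 raised by 2 log2 units were called, as were 32 of 50 lowered and 37 of 50 raised by 1, with 7 false calls. For IDR-1018 in brain, the corresponding numbers were 49, 48, 31 and 42 of 50, with 13 false calls. The simulated noise was drawn independently for each gene and held no differences between BeadChips. These numbers therefore test the scripts and do not give the error rates of the real arrays, where another split of the brain arrays called 1333 genes. The number of arrays per group limits the precision of every value: median signals ran from 107.9 to 169.8, and 17390 to 20394 probes (38.4% to 45.0%) had a detection p under 0.05 on an array.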

Results

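The samples came from female C57BL/6 mice of 8 weeks, a standard inbred laboratory strain. Infected mice received 100000 red blood cells carrying *Plasmodium berghei* ANKA, a rodent malaria parasite, into the peritoneum. IDR-1018, a compound given here by its code name, was injected into a vein every 48 h, starting 24 h before infection. Each dose was 8 mg per kg, and its volume of saline was 200 µL. The other infected mice had saline alone. Spleen and brain were taken on day 3 of infection. Each tissue therefore had 3 uninfected mice, 3 saline-treated infected mice and 9 IDR-1018-treated infected mice, with 17390 to 19123 probes detected per spleen array and 18744 to 20394 per brain array. The comparisons ask what infection changed in each tissue, what IDR-1018 changed in infected mice, and whether the tissues differed. The uninfected mice were untreated. Changes credited to infection below therefore cannot be told apart from effects of the repeated saline injections and handling.

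Infection was first compared in spleen, between saline-treated infected and uninfected mice. Genes that interferon-gamma induces rose strongly. Igtp, an immunity-related GTPase, rose by 2.44 ± 0.15 on the log2 scale (5.44-fold, 3 mice per group, limma adjusted p = 5.00e-07), and the guanylate-binding proteins Gbp2, Gbp10 and Gbp2b rose by 2.76 ± 0.22, 3.34 ± 0.28 and 3.75 ± 0.38. Ifng itself rose by 3.85 ± 0.35 (14.4-fold, adjusted p = 1.05e-05), from a mean log2 level of 6.14 ± 0.35 to 9.99 ± 0.27 (SD, n = 3 each). Of 25 measured interferon-gamma-inducible GTPases and effectors, 23 rose and none fell, as they did with p adjusted over the list alone. Their median change was 1.70 (1.64 with BeadChip as a block, 1.96 within BeadChip 2), with camera adjusted p = 2.56e-29 at the preset correlation and adjusted p = 0.0713 with an estimated correlation. In spleen BeadChip 2 alone held both groups, so each value within it sets saline-treated mouse 22 against uninfected mouse 38. The other saline-treated spleens were on BeadChips 1 and 4 and the other uninfected ones on BeadChips 3 and 5. Infection and BeadChip are therefore largely confounded. Of 32 interferon-stimulated genes, 25 rose (28 adjusted over the list alone), among them the antiviral genes Ifit3 and Mx2 by 2.52 ± 0.31 and 2.52 ± 0.35, and Parp14 by 1.52 ± 0.18. That list's median was 1.78 (1.86 blocked, 2.33 within BeadChip 2; adjusted p = 1.43e-24, and adjusted p = 0.132 with an estimated correlation).

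Antigen presentation, chemokines and the proteasome rose as well. Of 14 genes of MHC class I presentation, 10 rose (10 adjusted over the list alone), including the transactivator Nlrc5 (2.82-fold) and the peptide transporter Tap1 by 1.29 ± 0.15, and the immunoproteasome subunit Psmb9 by 0.91 ± 0.15. The median was 0.77 (0.75 blocked, 0.87 within BeadChip 2; adjusted p = 3.17e-08, and adjusted p = 0.154 with an estimated correlation). Of 31 cytokines and chemokines, 18 rose and 2 fell (19 and 4 adjusted over the list alone), with Ccl12, Cxcl10, Ccl7 and Cxcl9, which attract monocytes and T cells, up by 4.46 ± 0.40, 3.41 ± 0.36, 3.49 ± 0.39 and 3.01 ± 0.26. This list's median was 1.17 (1.19 blocked, 1.41 within BeadChip 2; adjusted p = 7.32e-09, and adjusted p = 0.178 with an estimated correlation). Of 26 proteasome genes, 12 rose (17 adjusted over the list alone), such as the core subunits Psma4 and Psma7 by 0.93 ± 0.15 and 0.85 ± 0.14. Their median of 0.40 (0.42 blocked, 0.49 within BeadChip 2; adjusted p = 1.48e-09) was the only shift past the threshold with an estimated correlation in this comparison (adjusted p = 0.0173). Serpina3f, a serine protease inhibitor gene, and Mmp13, a collagenase gene, rose by 3.43 ± 0.34 and 3.90 ± 0.60.

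Several other lists lay higher. Of 31 cell cycle genes, 6 rose (6 adjusted over the list alone), among them the replication genes Cdc45 by 1.36 ± 0.31 and Mcm6 by 0.97 ± 0.24, with a median of 0.74 (0.76 blocked, 1.00 within BeadChip 2). Its adjusted p was 1.29e-06, and adjusted p = 0.460 with an estimated correlation. Of 20 immediate-early genes, 4 rose (6 up and 1 down adjusted over the list alone), including the transcription factors Atf3 by 2.79 ± 0.35 and Jun by 0.94 ± 0.24, with a median of 0.46 (0.41 blocked, 0.44 within BeadChip 2) and adjusted p = 0.00571. With an estimated correlation that adjusted p was 0.178. Of 16 genes of cytotoxic T and NK cells, 6 rose (6 up and 2 down adjusted over the list alone), among them the lineage factor Tbx21 by 1.49 ± 0.22, with a median of 0.39 (0.31 blocked, 0.71 within BeadChip 2; adjusted p = 0.00859, and adjusted p = 0.406 with an estimated correlation). Glycolysis genes had a median of 0.22 (0.40 within BeadChip 2; adjusted p = 0.0192, and adjusted p = 0.163 with an estimated correlation), with 6 of 17 up (7 over the list alone), such as the phosphofructokinase gene Pfkp by 1.39 ± 0.23 and the lactate dehydrogenase gene Ldha by 0.52 ± 0.13. With BeadChip as a block that median was 0.28 and its adjusted p 0.0860. Oxidative phosphorylation genes had a median of 0.16 (0.19 blocked, 0.18 within BeadChip 2; adjusted p = 0.0326, and adjusted p = 0.178 with an estimated correlation), with 2 of 35 up, including Cycs by 0.76 ± 0.16. Fcgr1, a high-affinity antibody receptor of macrophages, rose by 1.84 ± 0.32.

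Other lists lay lower in the infected spleens. Of 15 genes of red pulp and marginal zone macrophages, 5 fell and none rose (7 fell adjusted over the list alone): the log2 changes were -3.31 ± 0.62 for the haemoglobin scavenger receptor Cd163, -1.69 ± 0.33 for the phosphatidylserine receptor Timd4 and -0.72 ± 0.14 for the iron exporter Slc40a1. The mannose receptor Mrc1, a macrophage gene of another list, fell by 2.06 ± 0.34. The median of the 15 genes was -0.37 (-0.35 blocked, -0.39 within BeadChip 2; adjusted p = 8.79e-04, and adjusted p = 0.163 with an estimated correlation). Of 17 B cell genes, 4 fell (5 adjusted over the list alone), among them the low-affinity IgE receptor Fcer2a (-1.23 ± 0.32) and the complement receptor Cr2 (-1.36 ± 0.36), with a median of -0.42 (-0.44 blocked, -0.55 within BeadChip 2; adjusted p = 8.43e-04, and adjusted p = 0.406 with an estimated correlation). Genes of platelets and megakaryocytes had a median of -0.54 (-0.56 blocked, -0.30 within BeadChip 2), with 2 of 14 down (3 adjusted over the list alone), including the platelet tubulin gene Tubb1 (-0.85 ± 0.22). For this list adjusted p = 0.00900, and adjusted p = 0.474 with an estimated correlation. Of 17 glucocorticoid-responsive genes, 6 fell and 2 rose (7 and 2 over the list alone), among them Tsc22d3 (-1.73 ± 0.25) and Ddit4 (-1.69 ± 0.24). The median was -0.39 (-0.34 blocked, -0.27 within BeadChip 2; adjusted p = 0.00859, and adjusted p = 0.114 with an estimated correlation).

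Lists named for brain cells were also lower in the infected spleens, and both of these calls were lost with the pancreas covariate described below. The astrocyte call was also lost with no filter on dim probes (adjusted p = 0.102). The angiopoietin receptor Tek and the tight junction gene Cldn5, both genes of endothelium in many organs, had changes of -1.20 ± 0.17 and -0.95 ± 0.17. Ndrg2, a gene of many differentiated cells, and the gap junction gene Gja1, a gene of many cell types, had changes of -1.07 ± 0.20 and -0.73 ± 0.18. Of 13 genes of the brain endothelium and pericyte list, 3 fell and 1 rose (7 and 1 over the list alone), with a median of -0.33 (-0.43 blocked, -0.47 within BeadChip 2; adjusted p = 0.0167, and adjusted p = 0.208 with an estimated correlation). Of 10 astrocyte list genes, 3 fell (3 over the list alone), with a median of -0.28 (-0.40 blocked, -0.48 within BeadChip 2; adjusted p = 0.0326, and adjusted p = 0.163 with an estimated correlation).

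Transcripts of the exocrine pancreas varied most. All 14 measured members of that list fell (14 adjusted over the list alone). The pancreas genes Cela2a, Clps, Try4, Pnliprp1 and Rnase1, which encode digestive enzymes or their cofactor, stood at -5.89 ± 1.09, -5.72 ± 1.09, -5.51 ± 1.12, -5.40 ± 1.06 and -5.26 ± 1.14. Each of these 5 genes was detected in 3 of 3 uninfected, 1 of 3 saline-treated and 0 of 9 IDR-1018-treated spleens. The list's median was -5.04 (-5.85 blocked, -9.76 within BeadChip 2; adjusted p = 5.42e-11, and adjusted p = 0.188 with an estimated correlation). It varied widely among uninfected spleens, at 3.86 in mouse 38, -0.57 in mouse 37 and -3.19 in mouse 40 relative to the mean of those mice, against -3.36 in mouse 23 and -5.90 and -5.72 in the other saline-treated mice.

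In all, 1899 of 14683 genes differed with infection in spleen at a limma adjusted p under 0.05, 1004 higher and 895 lower, of which 337 and 279 differed by over 2-fold. Among all 14683 genes tested, the values of the 2 groups did not overlap for 5084 (34.6%), against 10% by chance for 3 against 3. A fit with BeadChip as a fixed block called 1612 genes, 1290 of them shared. Of the 46 named genes 43 stayed past the threshold with that block, and Tubb1, Jun and Ldha did not (adjusted p = 0.0588, 0.107 and 0.0565). When only these 2 groups were fitted 8 named genes lost their call: Cela2a, Clps, Try4, Pnliprp1, Rnase1, Fcer2a, Gja1 and Ldha (adjusted p = 0.0592, 0.0630, 0.0734, 0.0674, 0.0882, 0.0757, 0.0748 and 0.0609). Without the 3 arrays of BeadChip 5, an alternative added after seeing the data, Gja1, Jun, Ldha and Tubb1 lost theirs (0.0513, 0.0942, 0.0685 and 0.0666), as did Gja1 with median scaling (0.0534). The block also lowered the number of called members from 12 to 5 for the proteasome, 6 to 3 for cytotoxic cells and 6 to 4 for glycolysis. That number went from 4 to 2 for immediate-early genes, 2 to 1 for oxidative phosphorylation and 2 to 0 for platelets. For MHC class I presentation it went from 10 to 9, and for rising cytokines and chemokines from 18 to 16. It rose from 25 to 26 for interferon-stimulated genes, 6 to 8 for the cell cycle, 4 to 6 for B cells and 5 to 6 for red pulp and marginal zone macrophages. Camera called 17 of 35 lists, 10 higher and 7 lower. Fry called 18, including 15 of these 17 but not the cell cycle and platelet lists (adjusted p = 0.0857 for each), and the exact permutation test gave each of the 17 its smallest possible p of 0.1.

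Several of these calls were lost when single mice were left out. Leaving out a mouse also leaves fewer in its group, so a lost call does not by itself show that it rested on that mouse. The count fell to 768 without the saline-treated spleen of mouse 24 (759 of them shared), 1081 without uninfected mouse 38, 1100 without saline-treated mouse 22 and 1160 without uninfected mouse 37. Without mouse 24, 7 named genes lost their call: Cdc45, Mcm6, Fcer2a, Cr2, Tubb1, Ldha and Gja1 (adjusted p = 0.0592, 0.0851, 0.119, 0.0776, 0.0563, 0.0782 and 0.0857). Mcm6, Fcer2a, Cr2 and Gja1 were lost without mouse 38 (0.0542, 0.0848, 0.0642 and 0.0636), and Cr2, Tubb1, Jun and Ldha without mouse 37 (0.10, 0.0697, 0.0825 and 0.0665). Fcer2a and Jun were lost without mouse 22 (0.0689 and 0.0642), and Cr2 without mouse 23 (0.0543). Called members of several lists also dropped without mouse 24, 38, 22 or 37. In that order they numbered 4, 7, 6 and 6 for the proteasome, 0, 1, 2 and 2 for the cell cycle, 1, 3, 3 and 2 for glycolysis, 0, 0, 1 and 1 for B cells, 0, 1, 2 and 0 for platelets, and 3 in each case for cytotoxic cells. MHC class I presentation had 7 called members without mouse 24 or 22 and 8 without mouse 38 or 37. The pancreas list had 6 without mouse 24 and 10 without mouse 22. The astrocyte list had 2 without mouse 24 or 22 and 1 without mouse 38, and immediate-early genes 2 without mouse 22. Oxidative phosphorylation had 1 called member without mouse 24, 22 or 37. For the interferon-gamma-inducible list the number stayed between 21 and 23, and for interferon-stimulated genes between 22 and 26. List calls were lost for astrocytes without mouse 38 (0.0824), oxidative phosphorylation without mouse 40, 24 or 22 (0.0728, 0.0656 and 0.0576), platelets without mouse 23 (0.0721) and cytotoxic cells without mouse 22 (0.0713).

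The pancreas transcripts were also set as a covariate, an alternative chosen after seeing the data. With the median of that list in the fit 40 genes passed, 32 higher and 8 lower, including 9 of the 25 interferon-gamma-inducible genes, where 23 had passed without it. Called members went from 25 to 0 for interferon-stimulated genes, 12 to 0 for the proteasome, 10 to 1 for MHC class I presentation, 18 to 4 for rising cytokines and chemokines, 6 to 1 for falling glucocorticoid-responsive genes, 4 to 1 for immediate-early genes and 6 to 1 for cytotoxic cells. All the other called lists of this comparison had 0. Of the 46 named genes 11 stayed past the threshold and 35 did not, of which 5 were pancreas genes. For 24 of the other 30 the change kept at least 0.75 of its size, while the standard errors of the 30 were 1.40 to 1.60 times as large. Tek, Slc40a1 and Psma7, for example, had changes of -1.23 ± 0.27, -0.72 ± 0.22 and 0.79 ± 0.22 with the covariate, whereas Fcer2a went to -0.56 ± 0.45 and Cela2a to -1.60 ± 0.90. The calls of the cell cycle, oxidative phosphorylation, B cell, astrocyte and brain endothelium lists were lost (adjusted p = 0.106, 0.117, 0.0675, 0.217 and 0.0990).

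**Figure D1:**
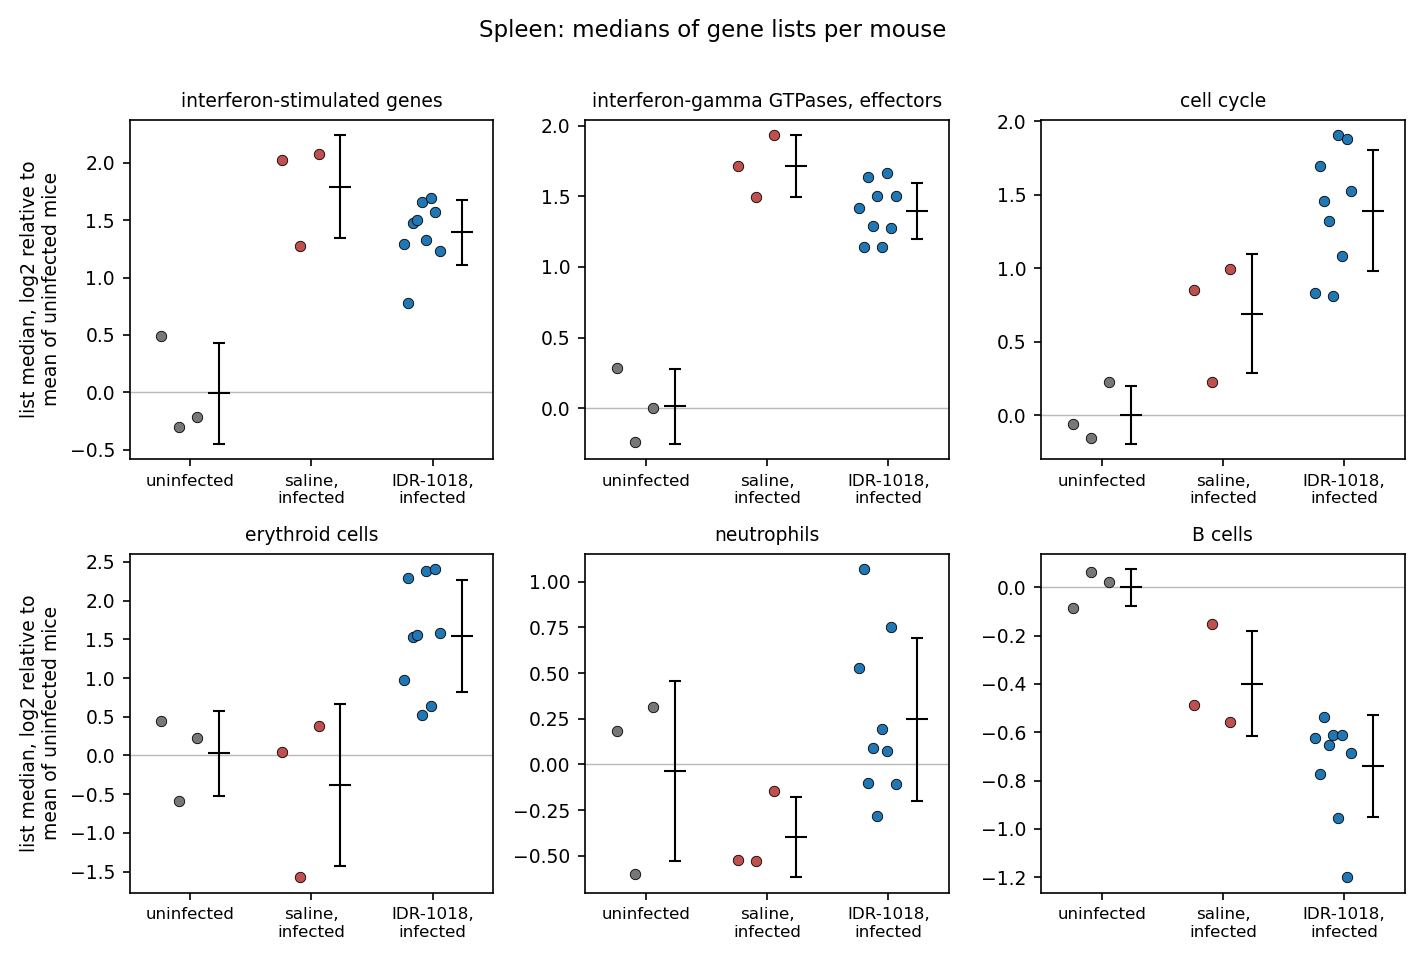
Medians of 6 gene lists in each spleen on the log2 scale relative to the mean of the uninfected mice (points, 1 per mouse; bars, mean and SD of 3 uninfected, 3 saline-treated infected and 9 IDR-1018-treated infected mice). The interferon-stimulated list lay at 1.27 to 2.08 in saline-treated and 0.78 to 1.70 in IDR-1018-treated mice, and the erythroid list at -1.57 to 0.38 and 0.52 to 2.41.

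**Figure D2:**
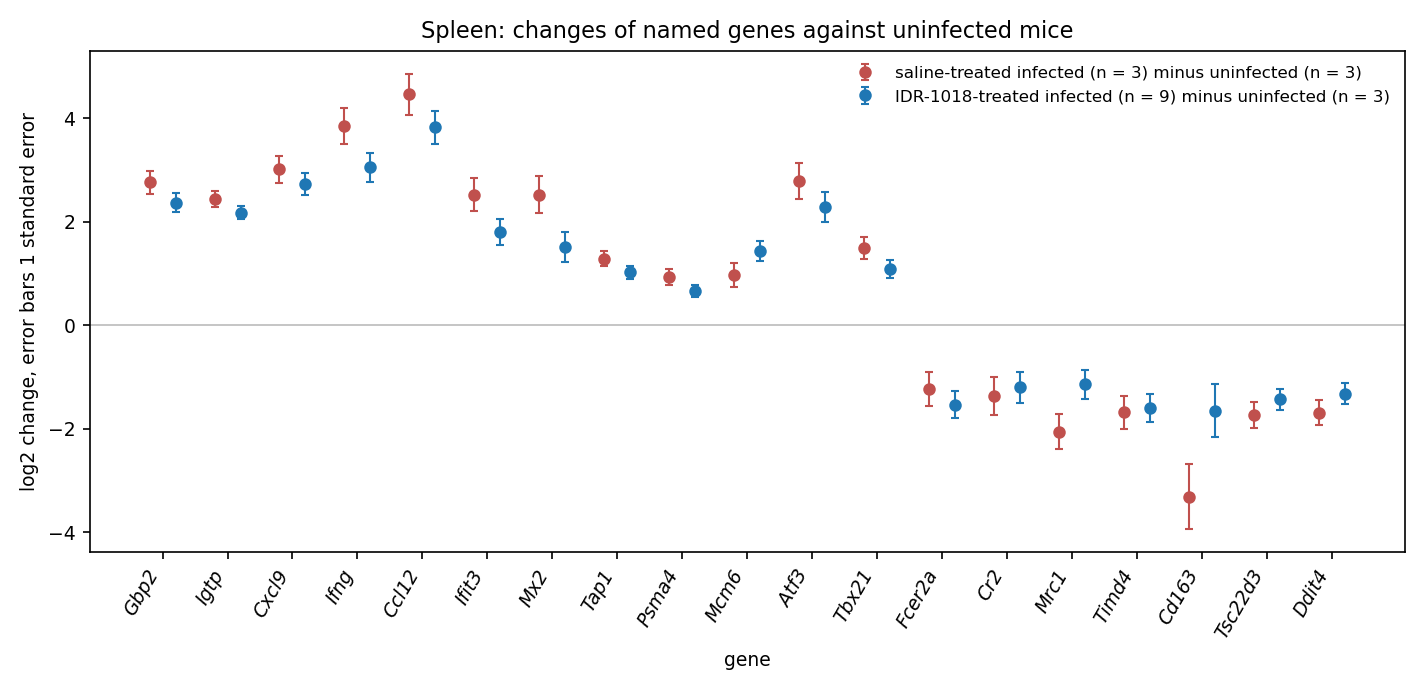
Log2 changes of 19 named genes in spleen against uninfected mice, in saline-treated (red) and IDR-1018-treated (blue) infected mice, with error bars of 1 standard error. Ccl12 was the highest in both groups, at 4.46 and 3.82, and Cd163 the lowest in saline-treated mice, at -3.31.

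IDR-1018 was the second comparison in spleen, between 9 treated and 3 saline-treated infected mice. Genes of red cell precursors were higher in all 9 treated mice than in every saline-treated mouse as a list, although no single gene passed the threshold. The 24 measured erythroid genes all had positive changes, with a median of 1.88 (1.73 with BeadChip as a block; 2.85, 1.52 and 1.58 within BeadChips 1, 2 and 4), and 23 passed when adjusted over the list alone (0 over all genes). Examples are Ank1, a protein of the red cell membrane skeleton, at 2.66 ± 0.60, the haem synthesis enzyme Fech at 1.43 ± 0.29, and the mitochondrial iron importer Slc25a37 at 1.39 ± 0.27. Camera gave adjusted p = 3.01e-25, and adjusted p = 0.198 with an estimated correlation; the exact permutation p was 0.00909, the smallest possible. Genes of haem, iron and oxidative stress had a median of 0.30 (0.34 blocked; 0.59, 0.20 and 0.25 within the BeadChips), 20 of 24 positive, including Nqo1 at 1.32 ± 0.29, the transferrin receptor Tfrc at 1.53 ± 0.36 and catalase (Cat) at 0.82 ± 0.18. For that list adjusted p = 2.25e-06, and adjusted p = 0.198 with an estimated correlation, with 9 genes up adjusted over the list alone.

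Proliferation and other blood lineages lay on the same side. All 31 cell cycle genes had positive changes, with a median of 0.66 (0.63 blocked; 0.95, 0.47 and 0.68 within BeadChips 1, 2 and 4) and 21 past the threshold adjusted over the list alone, such as the thymidylate synthase gene Tyms at 0.80 ± 0.20, the replication licensing gene Cdc6 at 1.26 ± 0.35, Kif23 at 0.79 ± 0.22 and Uhrf1 at 0.73 ± 0.20. Its adjusted p was 8.96e-17, and adjusted p = 0.406 with an estimated correlation. Neutrophil genes had a median of 0.70 (0.54 blocked; 0.74, 0.61 and 0.19 within the BeadChips), 15 of 18 positive and 6 past the threshold over the list alone, including the granule enzymes Mpo at 1.48 ± 0.49 and Prtn3 at 1.44 ± 0.52 and S100a9 at 0.84 ± 0.26. For this list adjusted p = 6.35e-06, and adjusted p = 0.406 with an estimated correlation. Platelet genes had a median of 0.38 (0.34 blocked; 0.77, 0.14 and 0.30), 13 of 14 positive and 2 past the threshold over the list alone, with the platelet chemokines Pf4 and Ppbp at 0.71 ± 0.34 (0.40 blocked) and 0.66 ± 0.19. Camera gave it adjusted p = 4.29e-04, and adjusted p = 0.419 with an estimated correlation. Oxidative phosphorylation genes, such as Ndufa4 at 0.23 ± 0.10, had a median of 0.12 (0.11 blocked; 0.14, 0.09 and 0.02; adjusted p = 0.00121, and adjusted p = 0.198 with an estimated correlation).

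Immune response genes lay lower in treated than in saline-treated spleens. These are levels in RNA of the whole sample, and dilution by erythroid RNA, taken up below, was not told apart. Interferon-stimulated genes had a median of -0.44 (-0.51 blocked; -0.01, -0.52 and -0.68 within BeadChips 1, 2 and 4), 1 of 32 positive and 2 below the threshold over the list alone, with Mx2 at -1.02 ± 0.29, Ifit3 at -0.73 ± 0.26 and Parp14 at -0.53 ± 0.15. The shift had adjusted p = 8.98e-06, and adjusted p = 0.458 with an estimated correlation. Interferon-gamma-inducible genes had a median of -0.28 (-0.32 blocked; -0.03, -0.43 and -0.54), with the inhibitory ligand Cd274 at -0.61 ± 0.17. The list's adjusted p was 7.53e-05, and adjusted p = 0.458 with an estimated correlation. MHC class I presentation had a median of -0.30 (-0.30 blocked; -0.29, -0.41 and -0.52), 5 of 14 past the threshold over the list alone with the class I heavy chain H2-D1 at -0.46 ± 0.12 and Nlrc5 at -0.37 ± 0.12. For this list adjusted p = 8.47e-05, and adjusted p = 0.406 with an estimated correlation. Cytokines and chemokines had a median of -0.44 (-0.45 blocked; -0.04, -0.28 and -0.67), with Ccl3 at -1.23 ± 0.29, Tnf at -0.83 ± 0.24 and Ifng at -0.80 ± 0.29. Camera gave it adjusted p = 1.45e-05, and adjusted p = 0.419 with an estimated correlation. Toll-like receptor and NF-kappaB genes, such as Relb at -0.53 ± 0.13, had a median of -0.26 (-0.30 blocked; -0.11, -0.25 and -0.09; adjusted p = 3.56e-05, and adjusted p = 0.406 with an estimated correlation).

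The other called lists had medians from -0.32 to -0.23. T cells (Cd3g at -0.39 ± 0.14; median -0.32, -0.29 blocked; -0.33, -0.23 and -0.09 within BeadChips 1, 2 and 4) and cytotoxic T and NK cells (Eomes at -0.65 ± 0.20 and Fasl at -0.61 ± 0.22; -0.28, -0.23 blocked; 0.21, -0.63 and -0.39) had adjusted p = 0.00121 and 0.00272, and adjusted p = 0.458 and 0.419 with an estimated correlation. B cells (Fcmr at -0.47 ± 0.15; -0.26, -0.19 blocked; -0.50, -0.17 and -0.19) and MHC class II (H2-DMb2 at -0.46 ± 0.14; -0.23, -0.25 blocked; -0.31, -0.20 and -0.08) had adjusted p = 0.00272 and 0.0120, and with an estimated correlation adjusted p = 0.458 for each. Immediate-early genes (Fosl2 at -0.35 ± 0.13; -0.32, -0.34 blocked; -0.11, -0.50 and -0.47) and complement (C1qb at -0.39 ± 0.13; -0.26, -0.30 blocked; 0.01, -0.29 and -0.35) had adjusted p = 0.0302 and 0.0291, and with an estimated correlation adjusted p = 0.419 for each.

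No gene passed limma's threshold for IDR-1018 in spleen: 0 of 14683 had an adjusted p under 0.05, the smallest was 0.0706, and 2451 had an unadjusted p under 0.05 (1164 higher, 1287 lower) where chance gives 734. At an adjusted p under 0.1 there were 245, of which 177 were higher. The smallest p-values belonged to Btnl10, a butyrophilin-like gene, at 2.65 ± 0.39 (0.0706), and to Cd59b, Gstm5, Prkar2b and Pvt1 at 1.46 ± 0.25, 1.80 ± 0.32, 1.56 ± 0.28 and 0.71 ± 0.12, and among lower genes to Themis2, Mndal and Gfi1 at -0.66 ± 0.12, -0.79 ± 0.15 and -0.75 ± 0.14 (adjusted p = 0.0847 for each of these 7). A fit with BeadChip as a fixed block called 147 genes (126 higher), as a random block 201, with array weights 671, and without the 3 arrays of BeadChip 5, an alternative added after seeing the data, 540. Leaving out the treated spleen of mouse 17 gave 169 genes, of mouse 13 gave 17, of mouse 19 gave 4, and of mouse 20 or saline-treated mouse 23 gave 1 each. Among all genes tested, the values of the 2 groups did not overlap for 591 (4.03%), against 0.909% by chance. Camera called 17 of 35 lists, 6 higher and 11 lower, of which 17 kept their call with BeadChip as a block and 15 kept their sign on all 3 BeadChips with both groups. Each of these BeadChips held 1 saline-treated spleen, so a value within a BeadChip rests on 1 saline-treated mouse. With an estimated correlation 0 lists passed, with fry 3 (erythroid, haem and iron, and oxidative phosphorylation) and with the exact permutation test 0 after adjustment, where 11 had an unadjusted p under 0.05. Without saline-treated mouse 23 the calls of MHC class II, T and B cells were lost (adjusted p = 0.186, 0.0549 and 0.208), without mouse 22 those of complement, cytotoxic cells and immediate-early genes (0.179, 0.229 and 0.0833), complement also with no filter on dim probes (0.114), and immediate-early genes also without mouse 24 or treated mouse 16 (0.0947 and 0.0523).

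The treated mice were also compared with uninfected mice in spleen. Interferon-gamma-inducible and interferon-stimulated genes were higher, with medians of 1.43 (22 of 25 up; 23 adjusted over the list alone) and 1.40 (25 of 32; 28), and Ccl12, Ifng, Tgtp1, Gbp2b and Serpina3f rose by 3.82 ± 0.33, 3.05 ± 0.29, 2.94 ± 0.34, 2.91 ± 0.31 and 2.86 ± 0.28. Adjusted p was 5.96e-22 and 7.43e-17 for these lists, and adjusted p = 0.108 and 0.168 with an estimated correlation. Cell cycle genes rose in 29 of 31 cases (29 over the list alone), with a median of 1.41, and erythroid genes in 17 of 24 (20 over the list alone), with a median of 1.57; adjusted p = 6.27e-19 and 4.46e-08, and adjusted p = 0.168 and 0.344 with an estimated correlation. Proteasome and oxidative phosphorylation genes were higher by 0.42 and 0.27 (17 of 26 and 11 of 35 up; 20 and 12 over the list alone; adjusted p = 2.07e-10 and 2.24e-05), and these kept their calls with an estimated correlation (adjusted p = 0.0124 and 0.0269). B cell genes fell in 13 of 17 cases (15 over the list alone) with a median of -0.74, T cell genes in 7 of 16 (10) with -0.50, and red pulp and marginal zone macrophage genes in 9 of 15 (10) with -0.54. Their adjusted p-values were 3.39e-07, 6.76e-04 and 8.68e-05, and adjusted p = 0.206, 0.344 and 0.108 with an estimated correlation. All 14 pancreas genes were lower, with Cela2a at least 135-fold lower because no treated spleen detected it, and Amy2a5, a pancreatic amylase gene, at -8.52 ± 1.01.

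Other lists past the threshold against uninfected mice were higher for cytokines and chemokines (median 0.72), MHC class I presentation (0.37) and glycolysis (0.31), and lower for brain endothelium and pericytes (-0.56), glucocorticoid-responsive genes (-0.40), MHC class II presentation (-0.36) and microglia (-0.29). Their adjusted p-values were 9.64e-05, 4.39e-04, 0.00648, 7.34e-04, 0.0180, 0.0146 and 0.0275, and adjusted p = 0.344, 0.325, 0.108, 0.118, 0.108, 0.443 and 0.344 with an estimated correlation. The pancreas list had a median of -5.81 (adjusted p = 2.10e-11, and adjusted p = 0.206 with an estimated correlation).

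In this comparison 3894 genes passed, 1772 higher and 2122 lower, and 2318 without uninfected mouse 38. With the pancreas covariate 4 passed. Camera called 17 of 35 lists, fry 23 and the permutation test 18. Of the 1004 genes that rose with infection, 785 (78.2%) also rose here, and of the 895 that fell, 798 (89.2%) also fell. Independent sets of these sizes would share 121 and 129. Groups without effects were also simulated by drawing from the residuals of all spleen arrays, with the same simulated uninfected group in both comparisons. There the comparisons shared a median of 0 and at most 317 and 702 genes. The simulation did not keep the real uninfected arrays. With 3 shared uninfected mice, which cannot be split into groups of 2, part of the excess may come from those arrays.

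Whether treatment moved infection-responsive genes back was asked with the correlation of the infection and IDR-1018 changes across genes, which are not independent replicates. In spleen r was -0.263 and the covariance -0.0496 (jackknife SD over arrays 0.0400). Simulated data with no effects, in which both comparisons share a simulated saline-treated group, gave a median r of -0.652 and a median covariance of -0.0340. Of 100 draws, 16 had a covariance at least as negative as the observed one. In brain r was -0.528 and the covariance -0.0231 (jackknife SD 0.0250), against -0.625 and -0.0266, with 63 of 100 draws as negative. The observed covariance exceeded the simulated one by -0.0156 in spleen and 0.00351 in brain, less than the jackknife SD in each tissue. Single mice moved the covariance widely: it was -0.0813 and -0.0747 in spleen without saline-treated mouse 23 or 22, and -0.0413 and -0.0402 in brain without mouse 24 or 23. In brain it was -0.0146 with the authors' deposited values and -0.0398 with median scaling. No simulation was run for these settings, so the comparison holds for all mice alone.

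In brain, the part of the brain sampled was the largest difference. Back samples had more of the hindbrain patterning genes Hoxa5, Hoxb5, Lhx1 and En2 (front minus back -4.74 ± 0.16, -4.65 ± 0.24, -5.25 ± 0.19 and -5.43 ± 0.34) and of the Purkinje cell gene Pcp2 (-6.42 ± 0.59), in 8 front against 7 back samples. Front samples had more of the striatal genes Rgs9 and Drd1 (3.50 ± 0.18 and 4.06 ± 0.28) and of the cortical factor Tbr1 (2.26 ± 0.17). In all 5082 of 15529 genes differed between front and back, 2538 higher and 2544 lower in front samples, and the part was a covariate in each brain comparison.

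Infection in brain was compared between 3 saline-treated infected and 3 uninfected mice. Interferon-responsive genes lay higher as lists, with no single gene past the threshold. Interferon-stimulated genes had a median of 0.95 (1.01 with BeadChip as a block), 22 of 23 positive and 12 past the threshold adjusted over the list alone (0 over all genes). Ifit3, Oasl2 and Usp18 had changes of 1.39 ± 0.32, 1.82 ± 0.46 and 1.65 ± 0.44. The shift had adjusted p = 9.65e-18, and adjusted p = 0.241 with an estimated correlation. Interferon-gamma-inducible genes had a median of 0.91 (0.91 blocked), 20 of 22 positive and 13 past the threshold over the list alone, with Igtp at 2.61 ± 0.59, Gbp2 at 2.56 ± 0.61, Irgm2 at 2.20 ± 0.48 and Gbp3 at 1.86 ± 0.39. The list's adjusted p was 1.53e-16, and adjusted p = 0.107 with an estimated correlation. MHC class I presentation had a median of 0.43 (0.39 blocked), 12 of 13 positive and 2 past the threshold over the list alone, with the immunoproteasome genes Psmb9 and Psmb8 at 1.37 ± 0.34 and 1.20 ± 0.34. For this list adjusted p = 5.55e-07, and adjusted p = 0.288 with an estimated correlation. The very large inducible GTPase Gvin1 and the membrane protein Ifitm1 stood at 2.62 ± 0.51 and 1.01 ± 0.22.

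Other brain lists lay lower with infection. Immediate-early genes, which neuronal activity induces, had a median of -0.44 (-0.26 blocked; 2 below the threshold over the list alone), with Fos at -2.49 ± 0.65, Arc at -1.91 ± 0.71 and Dusp1 at -1.39 ± 0.41 (-1.54, -0.93 and -0.84 blocked). Camera gave it adjusted p = 1.97e-05, and adjusted p = 0.497 with an estimated correlation. Glucocorticoid-responsive genes, such as Per1 at -0.63 ± 0.28, had a median of -0.19 (adjusted p = 0.0141, and adjusted p = 0.497 with an estimated correlation), and -0.10 with BeadChip as a block (adjusted p = 0.173). Neutrophil genes had a median of -0.48 (-0.65 blocked; adjusted p = 0.00111, and adjusted p = 0.497 with an estimated correlation), with S100a8 and S100a9 at -1.97 ± 0.86 and -1.41 ± 0.73; uninfected mouse 40 lay at 1.57 for this list, and without it the median was -0.11 (adjusted p = 0.494). The adult globin genes Hba-a1 and Hbb-bt stood at -1.11 ± 0.23 and -0.90 ± 0.20, and the haematopoietic and neuronal factor Gata2 at -0.89 ± 0.21.

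No gene passed limma's threshold for infection in brain (0 of 15529; smallest adjusted p 0.885), and 701 had an unadjusted p under 0.05 where chance gives 776. Camera called 6 of 34 lists, 3 higher and 3 lower; with an estimated correlation, fry and the permutation test 0 passed. With BeadChip as a fixed or random block the count of genes was 0. BeadChip 1 alone held both groups, as a back sample of a saline-treated and a front sample of an uninfected mouse, which differed by 1.29, 1.34, 0.54, -0.57, -0.21 and 0.10 for the lists in the order given. Without the saline-treated brain of mouse 23, 29 genes passed, all higher, and 20 of them belong to the interferon lists: examples are Gbp3 at 2.73 ± 0.21 (adjusted p = 6.89e-05), Gbp2 at 3.85 ± 0.39, Psmb9 at 2.06 ± 0.23 and Igtp at 3.72 ± 0.47. Mouse 23 had the only front sample of its group, and its interferon-stimulated list lay at 0.24 against 1.05 and 1.51 in the other saline-treated brains. In front samples alone, 1 saline-treated against 2 uninfected, that list had a median of 0.17 (adjusted p = 0.703) and MHC class I presentation 0.01 (0.875). In back samples alone, 2 against 1, the glucocorticoid list was lost (0.233), and neutrophil genes turned to 0.07 (0.919). With 1 sample on a side these values do not show that the part of the brain matters. The glucocorticoid list was lost without uninfected mouse 37 or saline-treated mouse 23 (adjusted p = 0.0536 and 0.0759), the neutrophil list also without mouse 23 (0.0522), and 10 or 11 lists were called without uninfected mouse 38 or saline-treated mouse 22. Scaling to the same median moved the all-gene median by -0.115 and gave 10 lists.

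**Figure D3:**
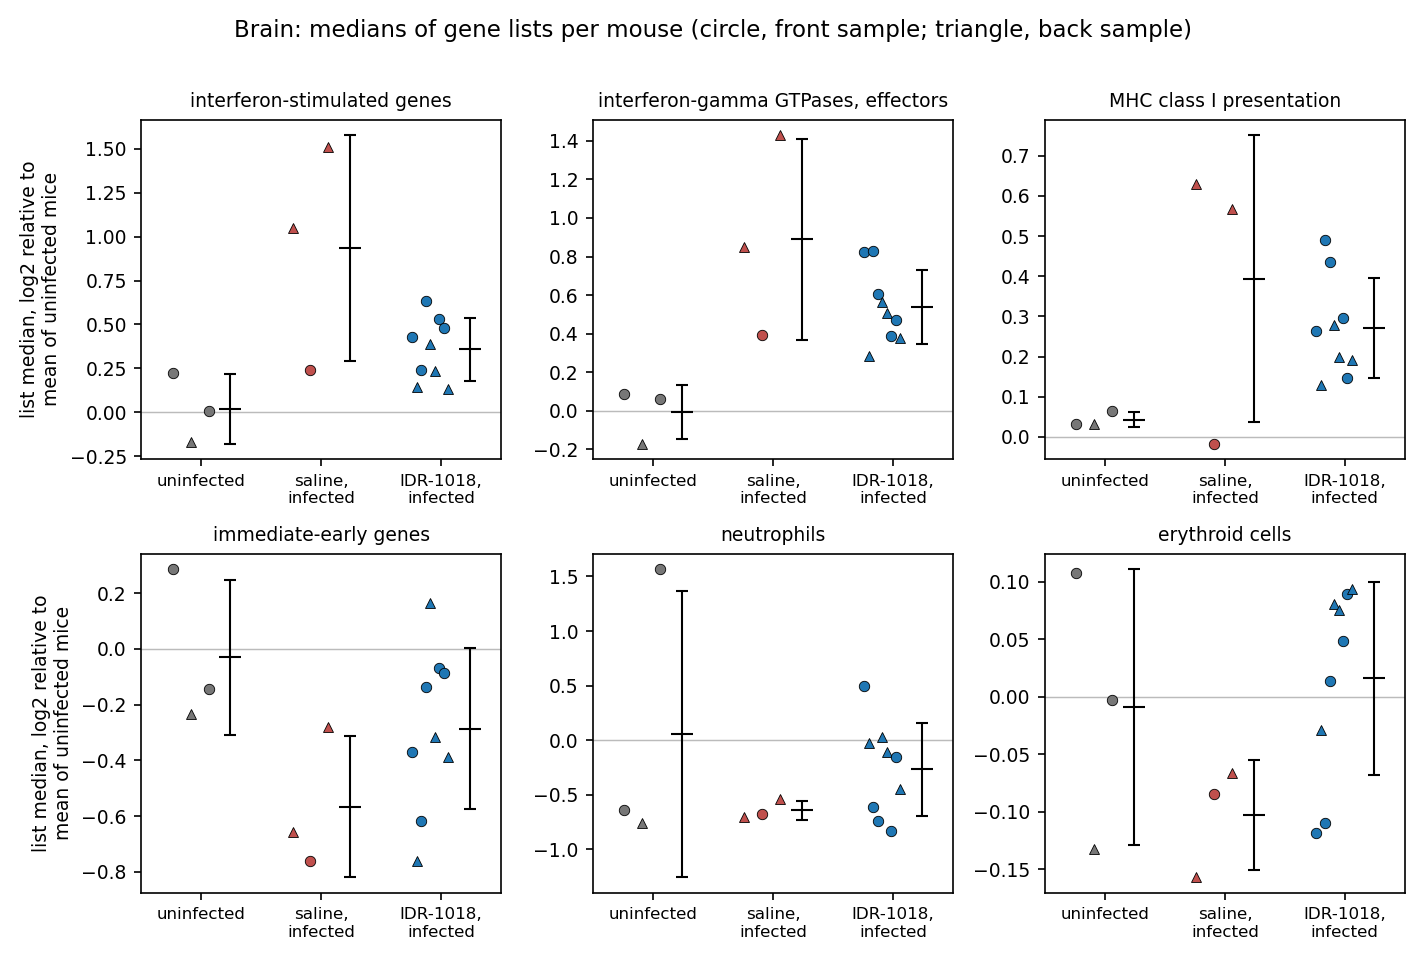
Medians of 6 gene lists in each brain on the log2 scale relative to the mean of the uninfected mice, after taking off the fitted front-back difference (circles, front samples; triangles, back samples; bars, mean and SD of 3 uninfected, 3 saline-treated infected and 9 IDR-1018-treated infected mice). The interferon-stimulated list lay at 0.24 in the 1 front sample of the saline-treated mice, at 1.05 and 1.51 in their back samples, and at 0.14 to 0.63 in IDR-1018-treated mice.

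IDR-1018 in brain was compared between 9 treated and 3 saline-treated infected mice. Interferon-stimulated genes had a median of -0.40 (-0.43 with BeadChip as a block), 1 of 23 positive, with Ifit3 at -0.84 ± 0.26 and Irf7 at -0.76 ± 0.29. The shift had adjusted p = 4.93e-13, and adjusted p = 0.339 with an estimated correlation. Interferon-gamma-inducible genes had a median of -0.37 (-0.37 blocked), with Cxcl10 at -1.25 ± 0.39 and Gbp3 at -0.79 ± 0.32. The list's adjusted p was 4.65e-05, and adjusted p = 0.439 with an estimated correlation. MHC class I presentation, with Psmb8 at -0.53 ± 0.28 and the class I light chain B2m at -0.25 ± 0.14, had a median of -0.25 (-0.17 blocked; adjusted p = 0.00143, and adjusted p = 0.498 with an estimated correlation). These shifts differed between BeadChips: within BeadChips 1, 3 and 5 they were -1.12, 0.29 and -0.86 for the interferon-stimulated list, -0.86, 0.32 and -0.30 for the interferon-gamma list and -0.29, 0.37 and -0.32 for MHC class I. BeadChip 3 held the front sample of saline-treated mouse 23, and in front samples alone, 5 treated against 1 saline-treated, the 3 medians were 0.37, 0.36 and 0.33. There Ifit3, Cxcl10, Gbp3, Psmb8 and B2m had changes of 0.10, 0.16, 0.55, 0.54 and 0.19, opposite in sign to those over all samples.

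Blood and vessel genes lay higher in treated brains. The erythroid list had a median of 0.09 (0.10 blocked; 0.15, 0.03 and 0.09 within BeadChips 1, 3 and 5), 14 of 17 positive and 2 past the threshold over the list alone, with the haem synthesis gene Alas2 at 1.69 ± 0.39 and the globins Hbb-bs, Hba-a1 and Hbb-bt at 1.02 ± 0.22, 0.97 ± 0.19 and 0.83 ± 0.16. For this list adjusted p = 5.39e-04, and adjusted p = 0.0536 with an estimated correlation. Neutrophil genes had a median of 0.48 (0.41 blocked; 0.57, 0.55 and 0.38), with S100a8 and S100a9 at 1.52 ± 0.70 and 1.31 ± 0.59. Camera gave it adjusted p = 0.00105, and adjusted p = 0.498 with an estimated correlation. Endothelial activation genes, such as Vwf at 0.65 ± 0.26 and Ackr1 at 0.24 ± 0.12 (0.13 blocked), had a median of 0.20 (0.18 blocked; 0.40, 0.23 and 0.05), and brain endothelium and pericytes, with Cldn5 at 0.29 ± 0.16, a median of 0.13 (0.10 blocked; 0.29, 0.09 and -0.03); adjusted p = 0.00482 and 0.00688, and adjusted p = 0.245 and 0.439 with an estimated correlation. Immediate-early genes (Fos at 1.67 ± 0.53) had a median of 0.23 (0.19 blocked; 0.45, 0.51 and -0.03; adjusted p = 0.0120) and choroid plexus genes (Otx2 at 0.45 ± 0.37) 0.24 (0.14, 0.26 and 0.25; adjusted p = 0.0237), and with an estimated correlation adjusted p = 0.642 for each. With BeadChip as a block the choroid plexus median was 0.17 and its adjusted p 0.0736. Forebrain genes, with Drd1 at -0.67 ± 0.35, Tbr1 at -0.40 ± 0.22 (-0.19 blocked) and Lamp5 at -0.30 ± 0.15, had a median of -0.17 (-0.12 blocked; -0.04, -0.25 and 0.17; adjusted p = 0.00272, and adjusted p = 0.498 with an estimated correlation). Without the covariate for the part of the brain, Drd1, Tbr1 and Otx2 turned to 0.23, 0.11 and -0.21. Oxidative phosphorylation, with Uqcrh at -0.20 ± 0.09, had a median of -0.07 (-0.11, -0.06 and 0.01; adjusted p = 0.0237, and adjusted p = 0.535 with an estimated correlation), -0.06 blocked with adjusted p = 0.191. With median scaling the list's median was 0.07 and Uqcrh stood at 0.13.

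No gene passed limma's threshold for IDR-1018 in brain (0 of 15529; smallest adjusted p 0.996), and 327 had an unadjusted p under 0.05 where chance gives 776; among these Tmsb10, an actin-binding peptide gene, stood at -0.43 ± 0.09. With BeadChip as a fixed or random block the count was 0, with array weights 5, and without saline-treated mouse 23 it was 4. Camera called 11 of 34 lists, of which 4 kept their sign on all 3 BeadChips, each of which held 1 saline-treated brain. With an estimated correlation, fry and the adjusted permutation test 0 passed. Without saline-treated mouse 23, 6 lists were called, and the calls of the neutrophil, endothelial activation, brain endothelium, immediate-early, choroid plexus and oxidative phosphorylation lists were lost (adjusted p = 0.135, 0.0612, 0.247, 0.622, 0.456 and 0.247). Without mouse 24 or mouse 22, 7 were called. The interferon-gamma, MHC class I and forebrain lists were lost without mouse 24 (adjusted p = 0.261, 0.382 and 0.150), and the MHC class I, endothelial activation, immediate-early and oxidative phosphorylation lists without mouse 22 (0.436, 0.107, 0.242 and 0.242). The choroid plexus list was also lost without mouse 24 (0.108) and without treated mice 15, 17, 18 or 19 (0.0675, 0.0687, 0.111 and 0.0800). Without treated mouse 17 the immediate-early and oxidative phosphorylation lists were lost (0.343 and 0.339), the latter also without treated mouse 20 (0.0741). Median scaling ended the calls of the endothelial activation, brain endothelium, immediate-early, choroid plexus and oxidative phosphorylation lists (adjusted p = 0.0742, 0.207, 0.207, 0.275 and 0.499). With no filter on dim probes the brain endothelium and choroid plexus lists were lost (0.0729 and 0.0588), the latter also with the stricter filter (0.110). In back samples alone, 4 treated against 2 saline-treated, the brain endothelium, immediate-early, forebrain and oxidative phosphorylation lists were lost (0.126, 0.220, 0.202 and 0.125), and in front samples alone the endothelial activation, erythroid, choroid plexus and oxidative phosphorylation lists (0.135, 0.0942, 0.0979 and 0.268), where mouse 23 was the only saline-treated sample, so a lost call there does not show that the part of the brain matters.

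Against uninfected mice, treated brains had interferon-gamma-inducible genes higher by a median of 0.51 (8 of 22 past the threshold over the list alone), interferon-stimulated genes by 0.42 and MHC class I presentation by 0.27. Adjusted p was 6.34e-11, 5.34e-06 and 0.00156, and adjusted p = 0.352, 0.653 and 0.653 with an estimated correlation. No gene passed limma's threshold (0 of 15529; smallest adjusted p 0.439), and 811 had an unadjusted p under 0.05 where chance gives 776. Endothelial activation and monocyte and macrophage genes had medians of 0.28 and 0.21, and immediate-early genes -0.37 (adjusted p = 0.0204, 0.0162 and 0.00363, and adjusted p = 0.364, 0.364 and 0.721 with an estimated correlation). A fit of the 2 groups alone called 5, and 5 were called without saline-treated mouse 23. Camera called 6 of 34 lists, and with an estimated correlation 0 passed.

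The difference between the tissues was tested directly. Ccl12, measured in both tissues, rose more with infection in spleen than in brain, by 3.27 ± 0.66 (adjusted p = 0.00435). Ifng, Gbp2b, Ccl7 and Mmp13 had differences of 3.58 ± 0.45, 3.84 ± 0.40, 3.26 ± 0.44 and 4.48 ± 0.88 (adjusted p = 3.09e-05, 2.70e-06, 7.20e-05 and 0.00354). These 4 genes were detected in 0, 0, 1 and 2 of the 15 brain samples, so their change in brain was not measured and the sizes of the differences are not exact. For Gbp2, Igtp, Psmb9 and Ifit3 the difference did not pass, at -0.10, -0.39, -0.53 and 0.90 (adjusted p = 0.963, 0.808, 0.489 and 0.301). The pancreas genes Clps, Cela2a and Try4 differed by -5.76 ± 1.17, -5.81 ± 1.19 and -5.49 ± 1.19 (adjusted p = 0.00466, 0.00492 and 0.00774), and were detected in 0, 1 and 0 brain samples. Over 17403 genes, 674 differed in their response to infection, 362 more positive in spleen and 312 less. Of these, 509 passed the detection filter in both tissues, 159 in spleen alone and 6 in brain alone. The count was 388 with BeadChip as a fixed block and 375 with the mouse as a block, and the largest effects of single mice were 308 without the brain of mouse 23, 311 without the spleen of mouse 24, 403 and 432 without the brains of mice 38 and 22, and 446 without the spleen of mouse 22. With median scaling, which moved the all-gene median by 0.137, it was 796, of which 587 (73.7%) were more positive in spleen, against 53.7%.

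For IDR-1018, 1 gene differed between the tissues, Btnl10, higher in spleen by 2.67 ± 0.43 (adjusted p = 0.0218; 0.0689 with BeadChip as a block and 0.112 with the mouse as a block). Btnl10 was detected in 0 of the 15 brain samples, so the size of that difference is not exact. At an unadjusted p under 0.05 there were 1658 genes, where chance gives 870. Ifit3 and S100a9 had differences of 0.23 and -0.43 (adjusted p = 0.905 and 0.899). With array weights 620 genes passed, and median scaling, which moved the all-gene median by -0.124, gave 0. Without the treated spleen of mouse 17 the count was 34, of mouse 19 it was 8 and of mouse 13 it was 2; without the brain of mouse 22, 23 or 24 or the spleen of mouse 24 it was 0. Btnl10 was lost without each of these and without the spleen of mouse 23 (adjusted p = 0.120, 0.106, 0.113, 0.0982 and 0.0857).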

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

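The tests of single patterns below were chosen after their results had been seen, except the test of islet hormones and the splits of samples for counts of genes past the adjusted threshold without a block, which were set down before. The tests of the part of the brain and of erythroid dilution were also replaced after results had been seen. The way a list was summarised per sample in the erythroid dilution test and in the brain interferon tests was also changed after results had been seen. It went from medians of levels to medians relative to the uninfected mean and, for brain, to medians of values centred per gene; values of the first and last measure are both given.

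Pancreas transcripts in spleen were the first pattern. The 14 exocrine genes moved together over the spleens (median pairwise r 0.982, lowest 0.754), as acinar tissue taken with some spleens would give. Islet hormone genes differed by a median of 0.778 between the spleen of uninfected mouse 38, which had the most exocrine RNA, and the other spleens, above the limit of 0.5 set before, but this decides little about islets: 3 of the 6 genes were detected in that spleen, Sst, which helps set the median, was detected in 0 spleens, and 3 of the 6 were higher in another spleen (Ins2 was detected in mouse 38 alone, at 8.35 against 4.78). Whether infection lowers these transcripts cannot be told apart from dissection: 3 mice against 3 give an exact two-sided permutation p of 0.1, the smallest possible, and although the 9 IDR-1018-treated infected spleens were also lower than the uninfected ones (mean -5.79, SD 0.08; exact p = 0.00909, adjusted p = 0.0177), the labels do not say how spleens were dissected, and a difference between infected and uninfected mice in that would give the same values. Cela2a, Clps and Try4 were detected in 0 of the 9 treated spleens. The SD of 0.08 may therefore reflect background more than likeness between mice. Acinar tissue in the samples may be the source of the pancreas transcripts, and this stays a hypothesis.

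The erythroid list in spleen, higher in IDR-1018-treated than in saline-treated mice, was the second pattern. Within BeadChips with both groups, each with 1 saline-treated spleen, its lowest difference was 1.52, which argues against a difference between BeadChips as the whole cause. Without the low saline-treated spleen of mouse 23 the median was 1.28 (camera adjusted p = 4.88e-17, and adjusted p = 0.272 with an estimated correlation, where the list did not pass with all mice either, at 0.198), and its size argues against that mouse alone. Dilution of all other cells alike would move their lists together. The differences of 9 other blood and immune cell lists had an SD of 0.334 (0.377 with medians of levels), reached by a share of 0.0364 (0.0591) of the splits of the 12 infected spleens. Neutrophil and platelet lists lay higher (0.644 and 0.408) and all others lower, from -0.340 for B cells to -0.038 for monocytes and macrophages. Their mean of -0.027 (SE 0.062) was not below 0 by over 2 standard errors, nor was that with medians of levels (-0.107, SE 0.094). Dilution cannot be told apart here because the shares fall on both sides of 0.05. An effect of IDR-1018 may underlie the pattern, as may differences between mice that the design does not name.

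Interferon-stimulated transcripts in brain, higher in saline-treated than in IDR-1018-treated mice, were the third pattern. Within back samples, where the part of the brain is constant, 2 saline-treated samples exceeded 4 treated ones by 1.15 (SE 0.184, two-sided exact permutation p = 0.0667, the smallest possible). With medians of levels the difference was 0.939 (SE 0.185, exact p = 0.0667). Treated back samples differed from treated front samples by -0.270 (SE 0.0931, exact p = 0.0317), or -0.215 (SE 0.151, exact p = 0.222) with medians of levels. These exact p-values are the share of splits with at least as large an absolute difference, whereas the permutation test of lists doubles the smaller tail. The part of the brain cannot give the difference within back samples, but 2 against 4 samples cannot give an exact p under 0.05. Differences between mice therefore stay open. Between back samples of BeadChips 1 and 5 the saline-treated sample was higher by 1.23 and 0.987 (0.751 and 1.18 with medians of levels). Each value sets 1 saline-treated mouse against 1 treated mouse. On BeadChip 3, which held front samples of both groups, the saline-treated sample was the lower one. Differences within BeadChips 1 and 5 argue against a difference between BeadChips as their cause, but cannot be told apart from differences between mice. All 5 treated front samples lay above the saline-treated front sample, so an effect alike in both parts was not seen, but that rests on mouse 23. An effect of IDR-1018 in the back of the brain may fit these values and was not tested apart from them.

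Of 154 sets of 9 IDR-1018-treated samples, 9 held a sample far from the others, and chance flags about 1 in 20 groups, or 7.7 here. In spleen these log2 levels were Cdc6 in mouse 13 (8.43, nearest 9.62), Mx2 in mouse 14 (8.60, nearest 9.43), Ppbp in mouse 14 (12.1, nearest 11.5), Slc40a1 in mouse 21 (14.0, nearest 13.7) and Tgtp1 in mouse 18 (7.82, nearest 9.07). Rnase1 stood apart in mouse 20 (4.89, nearest 4.64), where it was not detected. The spleen interferon-stimulated list of mouse 14 was 0.778, with the nearest at 1.23. In brain these levels were Irf7 in mouse 16 (5.796, nearest 5.34) and Tbr1 in mouse 17 (9.32, nearest 8.65).

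The response to infection differed between spleen and brain by an interaction test for 674 genes, among them Ccl12 (3.27), Ccl7 (3.26), Gbp2b (3.84), Ifng (3.58), Mmp13 (4.48), Clps (-5.76), Cela2a (-5.81) and Try4 (-5.49). Of the genes named here only Ccl12 passed the detection filter in brain. The response to IDR-1018 differed for 1 gene, Btnl10 (2.67; adjusted p = 0.0218, from 0.00302 to 0.147 over the alternatives), which was detected in 0 of 15 brains.

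Samples were also split in other ways. For infection in spleen 1 of 10 splits gave as many genes, the real one (1899, highest other 0), and for infection between tissues 1 of 10 (674, highest other 0). For the lists shifted by infection in spleen and brain it was 2 of 10 (17 against 18, and 6 against 6). The other splits called a median of 9 and 5 lists. With 10 splits no share under 0.05 can be had. For IDR-1018-treated against uninfected spleens 1 of 100 splits gave as many (3894, highest other 590), and for front against back brains 1 of 100 (5082, highest other 1). These shares lie under 0.05, which argues against chance for both, though not all of the 220 and 6435 possible splits were run. For IDR-1018 between tissues chance stays open (15 of 100, real count 1, highest other 91). Where the real count was 0 each split reaches it, so the splits say nothing about chance: this holds for infection in brain (10 of 10, highest other 0) and, with 100 of 100, for IDR-1018 in spleen (highest other 2), IDR-1018 in brain (1333) and IDR-1018-treated against uninfected brains (2). The split with 1333 and 91 genes set apart mice 14, 15 and 22, whose brain arrays share BeadChip 5, and so may reflect a structure of the samples. The real count of IDR-1018 in brain was 0 with and without BeadChip as a fixed block, which says nothing about the cause of that split. For the lists of IDR-1018 in spleen 8 of 100 splits gave as many (17, highest other 19), and in brain 1 of 100 (11, highest other 8). The median over the other splits was 6 lists in spleen and 3 in brain. The brain share lies under 0.05 for camera at its preset correlation with all mice. An estimated correlation, fry and the permutation test called 0, so chance stays open for that count. Without saline-treated mouse 23, 24 or 22 there were 6, 7 and 7 lists. Those fits held fewer saline-treated mice than the splits, so these counts cannot be set against the range of the splits. For IDR-1018 in spleen, genes at an unadjusted p under 0.05 (2451, highest other 2191) and genes with BeadChip as a fixed block (147, highest other 1) were each reached by 1 of 100 splits. Both were chosen after they had been seen, while the planned count was 0, so chance stays open for this comparison. Without saline-treated mouse 23 or 24 the number at an unadjusted p under 0.05 was 1695 and 1882. Those fits also held fewer saline-treated mice than the splits and cannot be set against them.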

How the results depend on the processing

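The main settings and most alternatives were chosen before the data were examined. Leaving out the 3 spleen arrays of BeadChip 5, the pancreas covariate, the permutation test of lists and the brain lists in front or back samples alone were chosen after seeing the data. Over the settings that left out an array, 2368 values of named genes and 726 of called lists kept their direction and side of the threshold, 23 and 39 lost their call, 39 and 0 gained one and none reversed. Over the other settings 1970 and 390 kept both, 64 and 162 lost their call, 82 and 0 gained one, and 10 and 7 reversed. The cause was not tested where none is named. Dim probes limit what can be seen, since as few as 38.4% of probes had a detection p under 0.05 on an array.

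For IDR-1018 in spleen, 147 genes passed with BeadChip as a fixed block (201 as a random block), and for the tissue differences 388 for infection and 0 for IDR-1018. With the mouse as a replicate block these last 2 counts were 375 and 0, and among named genes the block ended the call of Btnl10. With array weights the counts were 3271 for infection in spleen, 671 and 5 for IDR-1018 in spleen and brain, and 2107 and 620 for the tissue differences. Without the 3 arrays of BeadChip 5, 540 genes passed for IDR-1018 in spleen. With the pancreas covariate, which takes up a difference between the groups, 40 passed for infection and 4 for IDR-1018-treated against uninfected spleens. With 2 groups alone 5 passed for IDR-1018-treated against uninfected brains. For IDR-1018 between tissues the count was 0 with the authors' deposited values, without background correction, with median scaling and with no filter, and 2 with all probes.

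Lists called with an estimated correlation numbered 1 for infection and 0 for IDR-1018 in spleen, and 0 for each in brain. With fry they were 3 for IDR-1018 in spleen, and 0 for each comparison in brain, and with the permutation test 0 in all 4. Median scaling gave 10 lists for infection in brain. Reversed lists were exocrine pancreas in spleen with its own covariate (0.191), oxidative phosphorylation for IDR-1018 in brain with median scaling (0.0657) and, in front samples only, with 1 saline-treated sample, the interferon-stimulated, interferon-gamma and MHC class I lists for IDR-1018 (0.365, 0.362 and 0.326). For MHC class I with infection in front samples only camera's direction turned, while the median went to about 0 (0.00917) without changing sign. In back samples only, with 1 uninfected sample, neutrophils for infection in brain reversed (0.0737). All genes that reversed did so for IDR-1018 in brain: Uqcrh with median scaling (0.128), Psmb8 with array weights (0.0316), Drd1, Tbr1 and Otx2 without the covariate for the part of the brain (0.233, 0.106 and -0.210), and in front samples only Ifit3, Cxcl10, Gbp3, Psmb8 and B2m (0.0968, 0.162, 0.553, 0.538 and 0.194).

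Leaving out 1 array at a time gave 768 to 2014 genes for infection and 0 to 169 for IDR-1018 in spleen, 2318 to 4063 for IDR-1018-treated against uninfected spleens, and in brain 0 to 29, 0 to 4 and 0 to 5. The tissue differences ran from 308 to 896 for infection and 0 to 34 for IDR-1018. Lists ran from 16 to 20 and 14 to 18 in spleen and from 5 to 11 and 6 to 12 in brain. The correlation of infection and IDR-1018 changes ran from -0.404 to -0.208 in spleen and -0.694 to -0.411 in brain.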

Other observations

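The tests in this part were chosen after their results had been seen, and so were the genes named here. With BeadChip as a fixed block, 147 genes differed between IDR-1018-treated (n = 9) and saline-treated (n = 3) spleens at a limma adjusted p under 0.05, 126 higher and 21 lower. Of the 24 erythroid genes 10 passed, all higher: examples are the erythroid transcription factor Klf1 by 2.18, the membrane skeleton gene Add2 by 2.22, the erythropoietin receptor Epor by 1.73 and the carbonic anhydrase Car1 by 1.41 (adjusted p = 0.0349 for each). Tlcd4, also of that list, was higher by 2.50 (adjusted p = 0.0202). The ribonucleotide reductase gene Rrm2, needed for DNA synthesis, was higher by 1.23, and the cyclin gene Ccne2 by 1.26. Among the lower genes were the inhibitory ligand Cd274 (-0.66), the early activation marker Cd69 (-0.85) and the kinase Map3k8 (-0.56). Without the block no gene passed (0; 2451 at an unadjusted p under 0.05), and 110 of the 147 were shared with the 201 of the random block.

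Mice with more interferon-stimulated RNA in spleen may also have more in brain, a hypothesis tested over the 9 IDR-1018-treated mice. Pearson's r was 0.482 (exact permutation p = 0.191) and Spearman's rho 0.7 (exact p = 0.0433), and without mice 14 and 21, the farthest from the median in spleen, r was 0.423. Among 33 lists tested this way the smallest adjusted p was 0.620. With medians of levels r was 0.702 (exact permutation p = 0.0248), rho 0.567 (exact p = 0.121), r without mice 14 and 18 was 0.562, and the smallest adjusted p was 0.321. The measure of the list and the criterion, which was changed to require the adjusted p, were both altered after the result had been seen, and the relation stays open.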
